A study of Mus musculus with 6 samples.

How the data were processed

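RNA from 6 cultures of RAW264.7 macrophages, 3 with LPS and 3 with LPS plus the antibody 3A2, was measured by RNA sequencing. Per the labels' protocols, RNA was extracted with TRIzol and a column, ribosomal RNA was depleted, and strand-specific paired-end libraries were sequenced on an Illumina NovaSeq X. The authors deposited a table of raw read counts per gene symbol, with 1 column per library and no pooling of replicates. HISAT2 and edgeR are named without a version or a role, per the submitters' processing notes, and the counting program, the annotation and the strand setting are not given in the sources used here. The notes give GRCh38, a human build, while the symbols are those of mouse: 39282 of the 40773 symbols in the table match a RefSeq gene table of the mouse assembly GRCm38. No coordinates are therefore printed. Cells typed into 3 unnamed columns beside 3 genes were not used. No gene name was missing, since 0 entries named no gene.

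Groups and replicate numbers came from the labels, which state biological triplicates. A count was present for 18179 genes. Counts were filtered with filterByExpr, which left 11498 genes, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), by the robust quasi-likelihood F test of LPS plus 3A2 against LPS with no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM values were computed from the counts and the scaled library totals, those of Mmp14 over a group and its intervals from unscaled totals. Exact intervals are at the 95% level, and a count of 0 was taken to allow 3 counts, which is 0.404 to 0.495 CPM in a library. The biological coefficient of variation was 0.0768 and the median standard error of a log2 fold change was 0.119. For 44 genes with at least 10 counts, all 6 counts equal those of another gene, so reads of near-identical copies such as small nuclear RNAs cannot be assigned and their values are uncertain. Since the strand setting is not given, overlapping antisense genes are uncertain as well. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 3.46 to 23.5.

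Gene lists, 33 in all, were tested with camera (limma 3.58.1) on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists. The lists, the samples and tests, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule named Mmp14, genes past the threshold with large changes, and, in a list where no member passed, the most abundant tested member, with further members only in order of p up to 4 per list. Of the genes the rule names, a single gene is not reported here. Rnu5g, Tm6sf1, Pou2f2, Abhd5, Slc35a3 and Sltm fall outside this rule and were chosen after their values were seen. Mmp14 was below the filter and was kept in by hand for its own value.

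Alternatives were DESeq2 size factors within edgeR, totals without mitochondrial and the 20 most abundant genes, no filter, at least 1 CPM in all libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds, leaving out each library, camera with an estimated correlation, and fry. A pair of fits with a library-level covariate was added after the data were seen. The test was tried on simulated data, in 5 simulations with 200 changed genes each. There 0.071% of unchanged genes were called, and a list shifted by 1.2-fold was called in 5 of 5 simulations against 2 of 140 other lists. Simulated genes were drawn independently, so these rates do not cover lists whose members move together. The estimated correlation was 0.898 for mitochondrially encoded mRNAs, 0.451 for ribosomal proteins and 0.35 for histones. All splits of the 6 libraries into groups of 3 were also fitted, 10 in number.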

Results

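RNA was sequenced from RAW264.7 cells, a mouse macrophage line, kept for 24 h in lipopolysaccharide (LPS, 100 ng/mL), a bacterial cell wall component that activates Toll-like receptor 4. In the other group the same LPS dose was combined with 3A2, an antibody that neutralizes MMP14, given at 50 µg/mL. MMP14 is a membrane-bound matrix metalloproteinase that cuts collagen and activates other proteases. There were 3 biological replicates per group and 6 libraries in all. Libraries with LPS held 6844331, 7432553 and 6431096 counts, and those with LPS plus 3A2 held 6218086, 6537419 and 6060732. Between 14998 and 15309 genes had a count in a library. The comparison asks what neutralizing MMP14 changed in the transcriptome of LPS-treated macrophages. Cells without LPS and cells given a control antibody were not analysed here.

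Macrophages given LPS with 3A2 differed little in mRNA levels from macrophages given LPS alone, and most genes were bounded to small differences. Of 11498 genes tested, 0 were higher and 0 lower by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.295. At an unadjusted p under 0.05 there were 749 genes, 394 higher and 355 lower, where chance alone gives 575. Other splits of the same 6 libraries into groups of 3 gave 226 to 1575 such genes. DESeq2 called 1 gene, the spliceosomal RNA Rnu5g at 1.67-fold (adjusted p = 6.78e-06), and limma-voom called 0. Rnu5g measured 126 ± 28.4 CPM with LPS and 211 ± 9.61 CPM with 3A2, at an adjusted p of 0.719 by edgeR. By edgeR it passed with the replicate number as a block, at 6.09e-05, and without LPS replicate 1, at 0.000213. It passed without a filter on low counts as well, at 3.56e-16. The median absolute log2 fold change was 0.095. The 95% confidence interval of the fold change lay within 1.5-fold in either direction for 9147 genes (79.6%) and within 2-fold for 10819 (94.1%). All 3 libraries of a group lay beyond all 3 of the other for 1414 genes (12.3%), where chance gives 10%. In counts simulated on these libraries, the test recovered 90% of 2-fold changes, 63.6% of 1.5-fold changes and 21.5% of the smaller changes tried. Each simulation held 200 changed genes, and the Benjamini-Hochberg cutoff eases as more genes change. These rates therefore do not hold where few genes change. The simulations also lacked differences between libraries that many genes share. The result rested in part on LPS plus 3A2 replicate 2, since without it edgeR called 20 genes higher and 5 lower. Those higher included the mitochondrial mRNAs mt-Atp6, mt-Nd4l, mt-Nd2, mt-Nd5 and mt-Nd1. Mean mitochondrial mRNA, as log2 from the mean of all libraries, was -0.139 in replicate 2 and 0.114 and 0.45 in the other LPS plus 3A2 libraries. An effect of 3A2 on these calls cannot be told apart from that difference between libraries. Without a filter on low counts edgeR called 13 higher and 3 lower. Those also tested with the filter had nearly the same fold changes in both fits.

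Mmp14 mRNA, which encodes the antibody's target, was barely detected. The counts were 1, 5 and 0 in the LPS libraries and 2, 6 and 3 with 3A2. This is 0.29 CPM over the LPS group (exact 95% interval 0.106 to 0.631) and 0.585 CPM with 3A2 (0.292 to 1.05), and intervals cover counting error only. The library with 0 counts allows a level of up to 0.466 CPM. The ratio of the groups was 2.02, with a counting interval of 0.684 to 6.64, and an exact two-sided permutation test of the 3 against 3 libraries gave p = 0.4, where 0.1 is the smallest it allows. A difference was not detectable at this depth. Mmp14 lay below the filter on low counts. Kept in by hand, it had a log2 fold change of 0.99 (SE 0.869) and an adjusted p of 0.841 by edgeR. The antibody binds the protein, so the mRNA level does not check the treatment.

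Among the matrix metalloproteinases, ADAMs and TIMPs, Mmp12, the macrophage elastase, had the smallest p-value. It measured 47.9 ± 2.34 CPM with LPS and 67.8 ± 8.07 CPM with 3A2 (SD, n = 3), a fold change of 1.42 (95% interval 1.23 to 1.63) that was higher in 3 of 3 libraries than in any LPS library. It had the smallest unadjusted p of all genes, and its adjusted p was 0.295 by edgeR over all genes and 0.000468 adjusted over the list alone. Mmp12 passed over all genes by edgeR without LPS plus 3A2 replicate 2, at an adjusted p of 0.00136. It also passed without a filter on low counts, at 0.000326. Without the filter its log2 fold change was 0.507, against 0.503 with it, so that call does not reflect a larger difference. Mmp12 did not pass by edgeR with any other single library left out, at 0.0763 to 0.991. Nor did it pass with DESeq2 (0.169) or limma-voom (0.41). In all, 4 of 15 alternatives called it. Adam10, a membrane sheddase, stood at 1.15-fold (1.03 to 1.28). Adam8, the most abundant member, stood at 0.934-fold (0.854 to 1.02). Of 14 members tested, 7 lay above 0 and 7 below on the log2 scale, and the list as a whole was not called (camera adjusted p = 0.424).

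**Figure D1:**
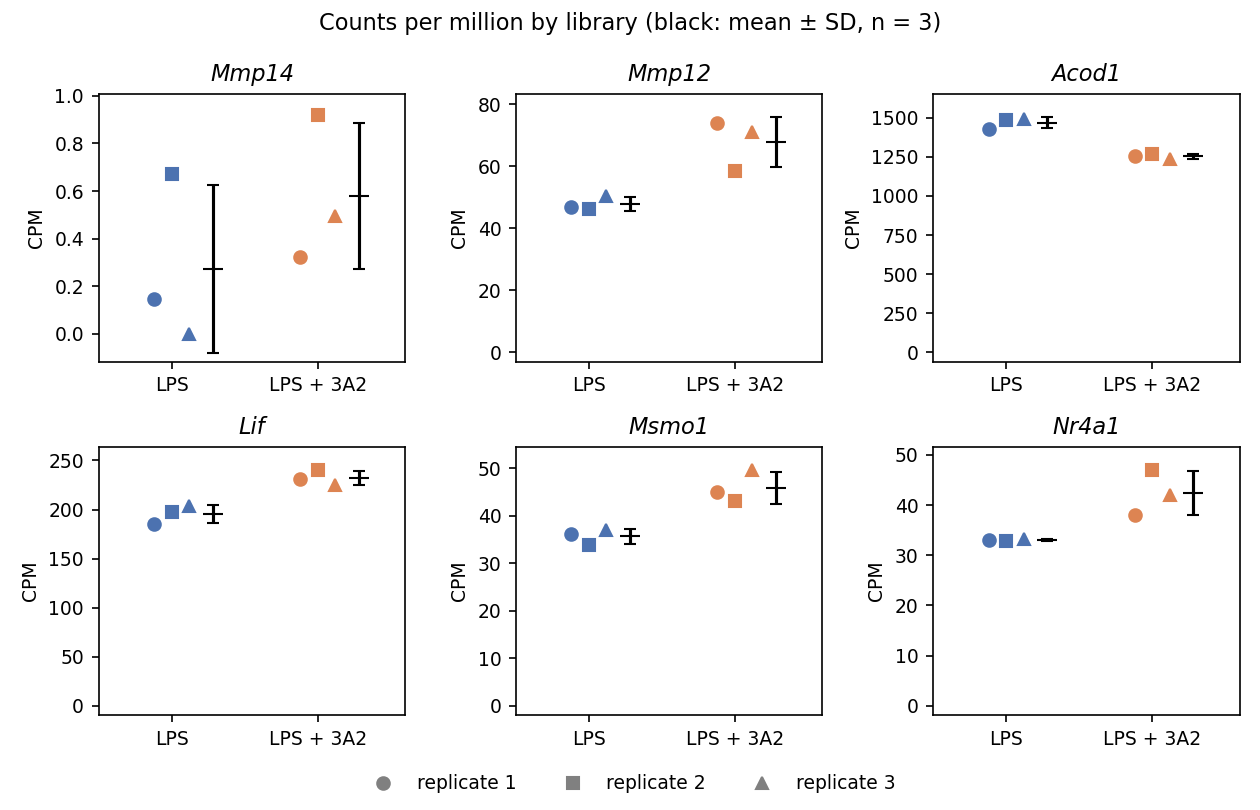
CPM of Mmp14 and of the 5 genes past the threshold over their own list, for each of the 6 libraries, with the group mean and SD in black (n = 3). Mmp12 averaged 47.9 CPM with LPS and 67.8 CPM with 3A2, while Acod1 averaged 1468 and 1252 CPM.

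No LPS response gene passed over all genes, and 2 passed within their list. Acod1, which makes itaconate in activated macrophages, measured 1468 ± 35.3 CPM with LPS and 1252 ± 16.8 CPM with 3A2, or 0.853-fold (95% interval 0.788 to 0.924). Lif, a cytokine of the interleukin-6 family, measured 195 ± 9.61 and 232 ± 7.43 CPM, or 1.19-fold (1.08 to 1.31). Both passed adjusted over the list alone by edgeR, at 0.00875 and 0.01, and neither passed over all genes, at 0.53 and 0.719. The acute-phase gene Saa3 stood at 0.682-fold (0.514 to 0.906). Ptgs2, the inducible cyclooxygenase and most abundant member, measured 1999 ± 81.9 and 2230 ± 268 CPM, or 1.12-fold. Of 19 proinflammatory cytokines and effectors, 9 lay above 0 and 10 below (camera adjusted p = 0.954).

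Chemokine mRNAs lay mostly above 0, in 10 of 13 tested members, with a median log2 fold change of 0.085, and the list was not called (camera adjusted p = 0.0689). It was called higher by camera without LPS plus 3A2 replicate 3, at an adjusted p of 0.0455, with DESeq2 at 0.033, and with the share of mitochondrial rRNA as a covariate at 0.0316. These calls use the preset correlation, and with all libraries the adjusted p was 0.786 with an estimated correlation. That form of camera called 0 lists in all, and the estimated correlation of the chemokines was -0.0802, below the preset 0.01. Its value therefore does not decide for or against this list. Ccl4 measured 512 ± 13.8 CPM with LPS and 572 ± 15.7 CPM with 3A2, or 1.12-fold. Ccl2, which attracts monocytes, stood at 1.2-fold (95% interval 1.02 to 1.42), and Ccl3, the most abundant, at 1.06-fold (0.976 to 1.14). The mixed form of fry, which asks whether members change in either direction, gave an adjusted p of 0.00632 for chemokines and 0.0464 for proinflammatory cytokines, and its directional form gave 0.11 and 0.989. Interferon-stimulated genes had 27 members above 0 and 16 below of 43 (camera adjusted p = 0.381). The antiviral gene Rsad2 stood at 1.21-fold (1.05 to 1.41), the nucleic acid sensor Zbp1 at 1.39-fold (1.07 to 1.8), and Irf7 at 1.02-fold (0.935 to 1.12). The 25 feedback regulators of Toll-like receptor signalling had 10 above 0 and 15 below (camera adjusted p = 0.353). Tnfaip3, which encodes the ubiquitin-editing enzyme A20, stood at 0.876-fold (0.787 to 0.976), and Nfkbia, the inhibitor of NF-κB, at 0.936-fold (0.858 to 1.02).

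Markers of alternative activation, adhesion genes and osteoclast genes were not called as lists. Il4ra, a chain of the interleukin-4 receptor, stood at 1.28-fold (95% interval 1.03 to 1.6) and Tgfb1 at 0.97-fold (0.876 to 1.07), and of 11 alternative activation markers 5 lay above 0 and 6 below (camera adjusted p = 0.794). Among 25 genes of extracellular matrix, integrins and adhesion, 12 lay above 0 and 13 below (camera adjusted p = 0.954). The integrin Itgav stood at 1.16-fold (1.05 to 1.29) and the hyaluronan receptor Cd44 at 1.14-fold (1.04 to 1.24). Spp1, which encodes osteopontin, was the most abundant member at 22210 ± 592 CPM with LPS and 22060 ± 712 CPM with 3A2. The 15 osteoclast genes had 6 above 0 and 9 below (camera adjusted p = 0.794), with Car2 at 1.06-fold (0.977 to 1.15).

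Lists of energy metabolism genes were not called by camera with all libraries and no covariate, and 0 members passed over all genes by edgeR. Glycolysis genes lay below 0 in 17 of 22 tested members, with a median log2 fold change of -0.035, and the list was not called (camera adjusted p = 0.237). Pfkl stood at 0.909-fold (95% interval 0.824 to 1) and Pkm, the pyruvate kinase of the pathway, at 0.951-fold (0.866 to 1.04). Without LPS plus 3A2 replicate 2 the glycolysis list was called lower, at a camera adjusted p of 0.00831 with the preset correlation. Without LPS plus 3A2 replicate 3 instead, the list stood at 0.878 by the same test. With all libraries its adjusted p was 0.9 with an estimated correlation. Nuclear genes of oxidative phosphorylation and the TCA cycle lay above 0 in 28 of 45 members (camera adjusted p = 0.492). With an index of mitochondrial over ribosomal mRNAs as a covariate this list was called higher, at a camera adjusted p of 0.0155 with the preset correlation. Without the covariate its adjusted p was 0.9 with an estimated correlation. For both lists that value comes from another fit than the call, and that form of camera called 0 lists. It therefore does not decide for or against either call. Cox5a, a subunit of cytochrome c oxidase, measured 149 ± 2.91 CPM with LPS and 174 ± 6.03 CPM with 3A2, or 1.17-fold. The coactivator gene Ppargc1b stood at 0.799-fold (0.671 to 0.952) and Atp5b at 1.02-fold (0.937 to 1.1).

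Lipid genes held 1 member past the threshold over its list. Msmo1, a sterol oxidase of cholesterol synthesis, measured 35.7 ± 1.64 CPM with LPS and 45.9 ± 3.34 CPM with 3A2 (SD, n = 3), or 1.29-fold (95% interval 1.12 to 1.48). Its edgeR p was 0.0326 adjusted over the list alone and 0.719 over all genes. The cholesterol biosynthesis and uptake list had 12 members above 0 and 12 below (camera adjusted p = 0.381). Of 29 genes of fatty acid uptake, oxidation and storage, 15 lay above 0 and 14 below (camera adjusted p = 0.794). Hilpda, a lipid droplet protein, stood at 1.24-fold (1.1 to 1.41) and the scavenger receptor Cd36 at 1.17-fold (1.04 to 1.31). Without LPS plus 3A2 replicate 2, Cd36 passed over all genes by edgeR, at an adjusted p of 0.0275 and a log2 fold change of 0.32. Its log2 fold change was 0.23 with all libraries, 0.12 without LPS plus 3A2 replicate 3 and 0.036 with an index of mitochondrial over ribosomal mRNAs as a covariate. Fatty acid synthesis genes had 6 above 0 and 8 below (camera adjusted p = 0.794), with Me1 at 0.844-fold and Scd2 at 0.963-fold. The 11 targets of LXR and genes of cholesterol efflux had 6 above 0 and 5 below (camera adjusted p = 0.954), with Npc2 at 1.02-fold.

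Antigen presentation, Fc receptor and lysosome genes were not called as lists. Of 21 antigen presentation and costimulation genes, 6 lay above 0 and 15 below (camera adjusted p = 0.751). B2m, the light chain of MHC class I, stood at 1.09-fold (95% interval 1.01 to 1.18). Fc receptors and complement had 7 above 0 and 8 below (camera adjusted p = 0.794), with the complement gene C1ra at 0.789-fold (0.645 to 0.965) and Fcer1g at 1.06-fold (0.953 to 1.19). The 33 lysosome and phagocytosis genes had 14 above 0 and 19 below (camera adjusted p = 0.794), and the protease gene Ctsb measured 1892 ± 35.2 and 1883 ± 24.2 CPM.

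Cell cycle and stress lists were not called, and their medians lay close to 0. S-phase genes lay above 0 in 21 of 30 members (camera adjusted p = 0.526), with Pcna at 1.08-fold (95% interval 0.974 to 1.2). Genes of G2 and mitosis had 15 above 0 and 15 below (camera adjusted p = 0.794), with Kif23 at 0.877-fold (0.792 to 0.971) and the proliferation marker Mki67 at 0.918-fold (0.842 to 1). The unfolded protein and integrated stress response list had 11 above 0 and 18 below (camera adjusted p = 0.381), and the chaperone gene Hsp90b1 stood at 1.01-fold (0.926 to 1.11). Oxidative stress targets of NRF2 had 11 above 0 and 9 below (camera adjusted p = 0.954), with ferritin Fth1 at 0.959-fold. Hypoxia targets had 16 above 0 and 8 below (camera adjusted p = 0.424), and Ldha measured 1843 ± 32.5 and 1845 ± 19.5 CPM. Targets of p53 and apoptosis genes had 15 above 0 and 10 below (camera adjusted p = 0.794), with Mcl1 at 0.982-fold. Inflammasome and pyroptosis genes had 8 above 0 and 7 below (camera adjusted p = 0.794), with Txnip at 0.998-fold. Nr4a1, an immediate early nuclear receptor, measured 33.1 ± 0.132 CPM with LPS and 42.4 ± 4.41 CPM with 3A2, or 1.28-fold (1.11 to 1.49). Its edgeR p was 0.0384 adjusted over the list alone and 0.719 over all genes. The immediate early list had 11 above 0 and 6 below of 17 (camera adjusted p = 0.311), with Ier3 at 1.05-fold. This list was called higher by camera without LPS plus 3A2 replicate 3, at an adjusted p of 0.0455, with the index covariate at 0.0155 and with the rRNA covariate at 0.0316. These use the preset correlation too, and with all libraries the adjusted p was 0.786 with an estimated correlation. That form of camera called 0 lists and was run on another fit than these calls, so its value does not decide on them.

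**Figure D2:**
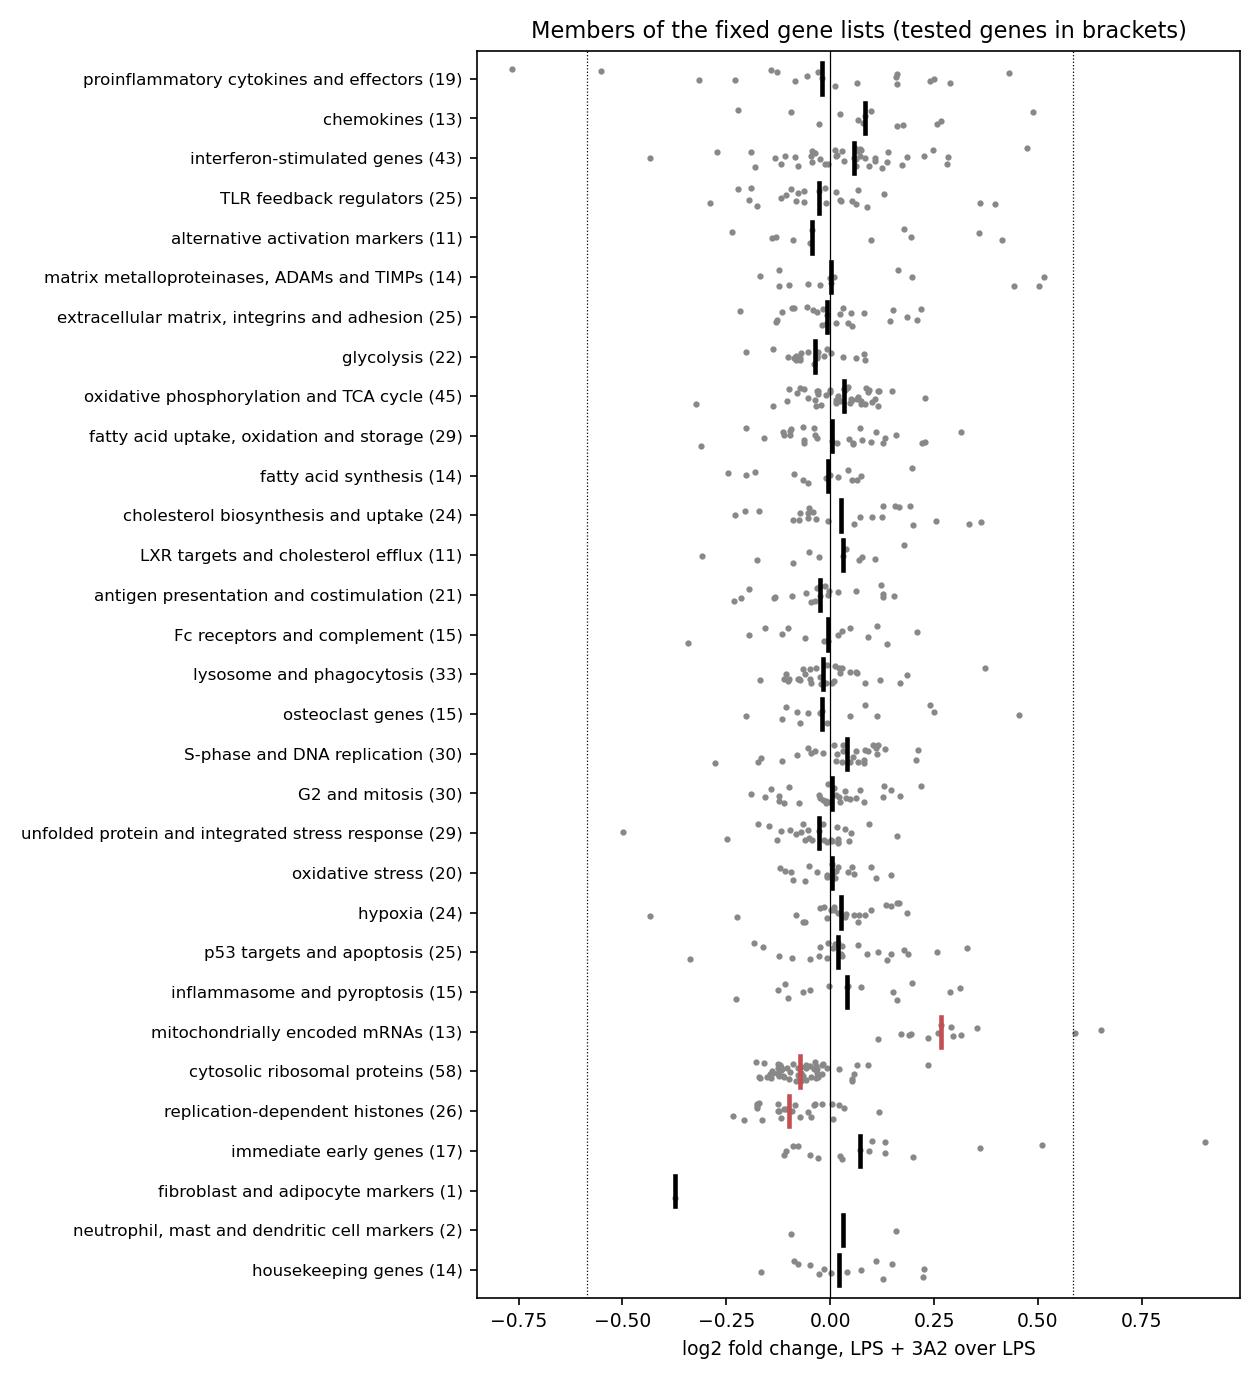
Log2 fold change of LPS plus 3A2 over LPS for each tested member (gray points) of the 31 fixed gene lists with a tested member, with the median of each list as a bar, red where camera called the list. Dotted lines mark 1.5-fold, and the medians furthest from 0 among called lists are 0.27 for mitochondrially encoded mRNAs and -0.099 for histones.

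Across these 25 lists of inflammatory, metabolic, proliferative, stress and immediate early genes, 555 different genes were tested and 0 of the lists were called by camera. Fold changes ran from 0.588 to 1.87. The median, the mean and the direction given by camera did not all share a sign for proinflammatory cytokines, alternative activation markers, adhesion genes, LXR targets, lysosome genes, osteoclast genes, G2 and mitosis genes and NRF2 targets. The 95% interval lay within 1.5-fold for 499 of the genes and within 2-fold for 542. In all, 5 members of 4 lists passed adjusted over the list alone and 0 passed over all genes by edgeR.

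Lists that follow RNA quality and library composition were called. Mitochondrially encoded mRNAs rose by camera with its preset correlation, with 13 of 13 above 0, a median log2 fold change of 0.27 and an adjusted p of 3.22e-11. With an estimated correlation the adjusted p was 0.786. Ribosomal protein mRNAs fell by camera, with 51 of 58 below 0, a median of -0.072 and an adjusted p of 8.49e-08. Histone mRNAs fell by camera as well, with 21 of 26 below 0, a median of -0.099 and an adjusted p of 0.000388. With an estimated correlation the adjusted p was 0.786 for each of these lists too. The most abundant members were mt-Co1 at 1.12-fold (95% interval 0.974 to 1.3), Rpl4 at 0.952-fold (0.877 to 1.03) and H1f4 at 0.918-fold (0.788 to 1.07). Those with the smallest p were mt-Nd4l at 1.22-fold, Rpl30 at 1.18-fold, against the direction of its list, and H1f2 at 0.889-fold. None of these passed over all genes by edgeR with all libraries and the filter on low counts. Without LPS plus 3A2 replicate 2 mt-Nd4l passed at an adjusted p of 0.00986 by edgeR, and without the filter at 0.0457. Its log2 fold change was 0.29 with all libraries and the filter, and 0.295 without the filter. It was 0.16 without LPS plus 3A2 replicate 3 and 0.067 with the index covariate, where mt-Nd4l did not pass. LPS plus 3A2 replicate 3 stood apart in each list. Without it the adjusted p by camera was 0.0565 for ribosomal proteins and 0.55 for histones, while mitochondrial mRNAs were still called, at 1.99e-07.

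**Figure D3:**
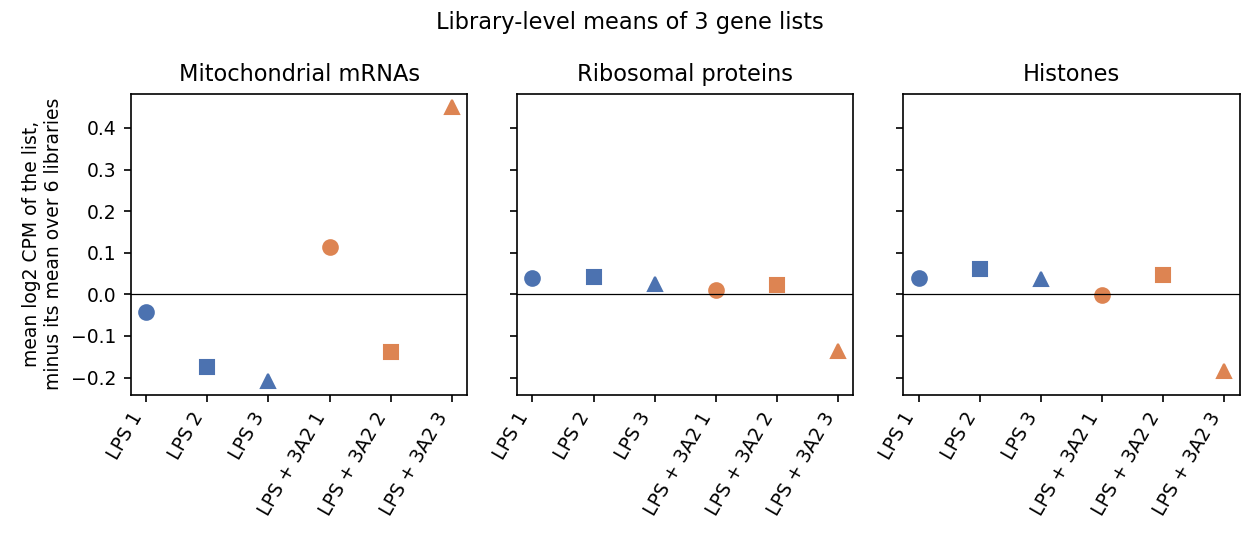
Mean log2 CPM of the mitochondrially encoded, ribosomal protein and histone mRNAs in each of the 6 libraries, after subtracting the mean over the libraries. LPS plus 3A2 replicate 3 lies at 0.45, -0.14 and -0.18.

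Markers of other cell types were near absent in both groups. Lymphocyte and plasma cell markers summed to at most 0.942 CPM in a library and epithelial markers to 0.155 CPM, and none was tested. Fibroblast and adipocyte markers summed to at most 4.51 CPM, and the only tested member, Acta2, stood at 0.772-fold (95% interval 0.454 to 1.31). Neutrophil, mast and dendritic cell markers summed to at most 10.1 CPM, with S100a8 at 0.936-fold (0.692 to 1.27). Camera gave adjusted p values of 0.794 and 0.954 for the lists with tested members. The 14 housekeeping genes had 8 above 0 and 6 below (camera adjusted p = 0.554), with Actb at 1.05-fold (0.969 to 1.15).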

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

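The covariate fits were chosen after the data were seen, and the other alternatives were planned. No gene was called in LPS plus 3A2 against LPS under DESeq2 size factors, totals without the most abundant genes, at least 1 CPM in all libraries or limma-voom. The stricter thresholds could only give 0 as well, so they do not test the result. Other settings gave calls, higher then lower: 13 and 3 with no low-count filter, 1 and 0 with DESeq2, 14 and 14 with the mitochondrial-ribosomal index as covariate, and 6 and 5 with the mitochondrial rRNA share as covariate. Genes called without the filter that were also tested with it had nearly the same fold changes in both fits. Leaving out 1 library gave 0 to 20 higher and 0 to 5 lower. There were 20 and 5 without LPS plus 3A2 replicate 2, 1 higher (Rnu5g) without LPS replicate 1 and 1 lower without LPS plus 3A2 replicate 3. The cause was not tested. With the replicate number as a block, 1 gene was higher, again Rnu5g, and 0 lower. Deviations of same-numbered libraries correlated at -0.00653, 0.0318 and -0.156. They gave no sign that the numbers pair the samples, and with so few libraries a pairing cannot be excluded. Mmp14 was called in no alternative, with log2 fold changes from 0.475 to 2.69. Another scaling moved the median log2 fold change of all genes to 0.00495 at most. Every scaling used centres most genes near 0, so a shift of all genes would not show in this value. Camera called 3 lists, 4 with DESeq2 and without LPS plus 3A2 replicate 2, 2 with the index as covariate, 5 with the rRNA share as covariate, 0 with an estimated correlation and 0 with directional fry. For mitochondrial mRNAs, ribosomal proteins and histones the adjusted p was 0.786 in each with an estimated correlation, 0.612, 0.612 and 0.631 by fry, and 0.434, 0.434 and 0.454 by its mixed form. With the index as covariate, which is built from the mitochondrial and ribosomal lists, the 3 directions turned, at 0.784, 0.848 and 0.607. Leaving out 1 library gave adjusted p values of 6.49e-22 to 1.99e-07 for mitochondrial mRNAs, 2.81e-10 to 0.0565 for ribosomal protein mRNAs and 2.96e-06 to 0.55 for histone mRNAs, the highest for ribosomal proteins and histones without LPS plus 3A2 replicate 3. Depth limits low genes such as Mmp14, with 17 counts in all.

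Signs turned for named genes that were never called. With the mitochondrial-ribosomal index as covariate the log2 fold changes were -0.00987 for Ptgs2, 0.0851 for Tgfb1, 0.0552 for Pkm, -0.0219 for Pcna, -0.0692 for Hsp90b1, -0.0569 for mt-Co1 and 0.0889 for H1f4. With the mitochondrial rRNA share as covariate the log2 fold changes were 0.00807 for Tgfb1, 0.00153 for Ctsb, -0.0294 for Hsp90b1 and 0.00247 for Txnip. With no low-count filter the log2 fold changes were 0.000539 for Txnip. Leaving out 1 library at a time gave log2 fold changes of -0.116 to 0.0284 for Tgfb1, -0.0317 to 0.0167 for Spp1, -0.00119 to 0.0384 for Atp5b, -0.0117 to 0.0588 for Npc2, -0.021 to 0.00432 for Ctsb, -0.0195 to 0.0681 for Hsp90b1, -0.012 to 0.012 for Ldha, -0.0138 to 0.0155 for Txnip, -0.217 to 0.0127 for H1f4 and -0.166 to 0.0116 for S100a8.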

Other observations

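The tests of other splits, of the gradient across libraries and of LPS plus 3A2 replicate 3 were chosen after the results were seen, and so were the bounds they were read against. The following genes outside the lists, among those with the smallest p-values, were chosen after their values were seen. Pou2f2, a transcription factor of the POU family, measured 79.1 ± 3.94 CPM with LPS and 59.8 ± 2.61 CPM with 3A2, or 0.756-fold (95% interval 0.673 to 0.85). Tm6sf1, a transmembrane protein gene, measured 80.9 ± 2.85 and 104 ± 1.24 CPM, or 1.28-fold (1.15 to 1.42). Abhd5, an activator of triglyceride lipolysis, measured 88.1 ± 1.89 and 111 ± 2.35 CPM, a log2 fold change of 0.33 (SE 0.0718). Slc35a3, a Golgi nucleotide-sugar transporter, stood at 1.43-fold (1.21 to 1.69) and Sltm at 0.796-fold (0.711 to 0.892). With all libraries and the filter on low counts none passed over all genes by edgeR, with adjusted p values of 0.295, 0.295, 0.514, 0.53 and 0.53 in that order. Without LPS plus 3A2 replicate 2, Slc35a3 passed by edgeR at an adjusted p of 0.00113, and Pou2f2 and Tm6sf1 at 0.0447 each. Without the filter Slc35a3 passed by edgeR at 2.95e-05, Pou2f2 at 0.0147, Tm6sf1 at 0.0176 and Abhd5 at 0.0457. Their fold changes hardly moved, so these calls do not reflect larger differences. For Slc35a3 the log2 fold change was 0.522 without the filter and 0.518 with it. Its unadjusted edgeR p was 3.24e-09 and 0.000322. Any split matches or exceeds the count of 0 genes, so the 10 of 10 splits that did say nothing about chance, and the highest other split called 2.

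With its preset correlation camera called mitochondrial mRNAs higher, and ribosomal protein and histone mRNAs lower, with 3A2, and with an estimated correlation the adjusted p was 0.786 for each. The mitochondrial mean spanned 0.589 on the log2 scale within the LPS plus 3A2 group against a difference of 0.283 between groups (exact permutation p = 0.2), so a gradient across libraries that does not follow the treatment may account for it, and without LPS plus 3A2 replicate 3 the difference was 0.129, with the list still called (camera adjusted p = 1.99e-07). For ribosomal proteins a share of 0.271 of the group difference was left without LPS plus 3A2 replicate 3, and for histones 0.259, with neither list still called, which is in line with that library as the source, although the ribosomal means of the groups did not overlap (exact permutation p = 0.1, the smallest possible). As many lists were called in 7 of the 10 splits, the real split calling 3 and the highest other 5, and 10 splits are too few for a share under 0.05. An effect of the antibody on these transcripts stays open, as untested.

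The members past the threshold over their list alone were Mmp12, Lif, Msmo1, Nr4a1 and, in the lower direction, Acod1. The log2 fold changes with the index of mitochondrial and ribosomal mRNAs as covariate had a median ratio of 0.896 to those without, from 0.737 for Msmo1 to 1.21 for Lif. There Acod1, Lif and Mmp12 passed over all genes by edgeR, at adjusted p of 0.00461, 0.00389 and 0.0466. Msmo1 and Nr4a1 did not, at 0.46 and 0.143, and without the covariate each stood at 0.719. The median ratio without LPS plus 3A2 replicate 3 was 0.956, from 0.84 for Msmo1 to 1.09 for Lif. None passed over all genes by edgeR without it, at adjusted p from 0.0599 to 0.773, and none had passed with it. Every gene kept its direction in both fits. These 5 genes were picked for small p-values on all 6 libraries, which favours fold changes that do not rest on a single library. The ratios therefore do not decide whether that library, or the gradient as the index measures it, is the source. Nor do the ratios bear on chance. A count of such members as large arose in 2 of the 10 splits. LPS replicate 1 with LPS plus 3A2 replicates 1 and 3 against the rest gave 22 members against 5. This points to a structure of the samples that the groups do not hold. Mitochondrial rRNA made up 5.13, 4.9 and 6.89% of counts in those libraries and 3.72, 2.64 and 3.01% in the rest. That split also had the largest difference in mean mitochondrial mRNA, 0.347 on the log2 scale against 0.283 for the real one. Neutralizing MMP14, or the presence of any antibody, may lie behind these genes as a hypothesis, and neither was tested apart since no control antibody was analysed here.

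With the mitochondrial-ribosomal index as covariate 28 genes were called, and 11 with the mitochondrial rRNA share, 8 of them shared and each in the same direction in both fits. They include Mmp12, Lif, Acod1, Tm6sf1, Pou2f2 and Abhd5. A count of 28 arose in 1 of the 10 splits, the real one, with 15 as the highest other, and 10 splits are too few for a share under 0.05. With the rRNA share another split called 47 genes against the real 11, so these calls may come from the covariate in so few libraries as much as from 3A2. Which of these holds cannot be told apart here.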
